A study of Homo sapiens with 4 samples.

How the data were processed

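RNA sequencing of CAL-27, an established human oral squamous cell carcinoma line, was analysed in 4 libraries. Per the labels' protocols, cells were infected either with an empty puromycin-resistance lentivirus (vector, 2 libraries) or with the same lentivirus carrying human ZNF750 (ZNF750, 2 libraries). Total RNA was column-purified and standard Illumina libraries were sequenced on an Illumina HiSeq instrument, per the labels' protocols and the series' design text. The labels do not say whether the libraries of a group came from separate flasks, infections or days, and they give no batch. All p-values therefore measure only the spread between these libraries, which may be technical.

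A table of raw counts per gene and a table of RPKM values were deposited for the whole series. The submitters' processing notes name TopHat2 2.0.9, DESeq 1.10.1 and the GRCh37 and hg19 builds, without saying which step each served. The counting tool, the gene annotation and the strand setting are not given in the sources used here. The deposited counts are whole numbers for 50582 Ensembl gene identifiers. Of these, 25960 had a count in any library. Each line carried a gene identifier, so there were 0 lines of totals or unassigned reads. The deposited RPKM values were checked against the counts. For all 25960 genes with counts they equalled the count divided by a fixed whole-number gene length and by the library's total, within a relative tolerance of 1e-06, so they carry no normalization beyond depth and length. Library totals in the count table were 8944858 and 8571857 for the vector libraries and 8109573 and 8266130 for the ZNF750 libraries. At these depths 1 CPM corresponds to between 8.15 and 8.81 counts, so genes near 1 CPM are measured with large counting error.

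Gene symbols came from a reference list of gene names and, where it gave none, from GENCODE release 29, both matched by identifier alone. Release 29 is a GRCh38 annotation, which differs from the build named in the notes. A match was found for 49481 identifiers (97.8%), and the 1101 without a name held at most 0.109% of the counts of any library. Coordinates are given only for ZNF750, on GRCh38. Without a stated strand setting, reads from overlapping or antisense genes cannot be told apart, and reads from near-identical family members may have been split or dropped during counting. Values of metallothionein, histone, S100A, SAA, SERPINB, keratin, AKR1C, IFITM, HLA and ribosomal protein genes are uncertain for that reason. Reads from the introduced and the endogenous ZNF750 gene are counted together.

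The comparison was ZNF750 minus vector over all 4 libraries. edgeR 4.0.16 (R 4.3.3) was used with filterByExpr (minimum count 10), TMM factors and the quasi-likelihood F test. The median prior degrees of freedom were 2742.2, so the p-value of a gene rests almost wholly on a spread pooled over genes. Its own spread between 2 libraries per group counts for little. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Expression levels are TMM-scaled CPM with the SD over 2 libraries. The standard error of a log2 fold change is its absolute value divided by the square root of its F statistic. Adjusted p-values under 1e-300 were recorded as 1e-300. The ZNF750 ratio has an exact 95% conditional binomial interval, which covers counting error only.

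Before the data were examined, 25 gene lists were fixed from textbook knowledge of squamous epithelium, tumour vasculature, the cell cycle, stress and metabolism, with markers of other cell types a culture might hold. Genes named from the data are ZNF750, the 12 largest rises and 12 largest falls, and up to 4 members of each list with the smallest p. Rises and falls were ranked among genes past the threshold with a mean of at least 5 CPM, groups that did not overlap and a standard gene symbol. All partners of ZNF750 could be named. This rule gave 120 distinct genes, and any other named gene was chosen after its values were seen. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 20 lists tested. Camera with a correlation estimated from these libraries and fry were run beside it. The estimated form takes its degrees of freedom from the 4 libraries rather than from the genes, so small p-values are hard for it to reach. A further 10 lists were written after the gene results had been seen and are used only in the closing observations.

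Alternative settings were DESeq2 size factors, upper-quartile factors or library size alone in place of TMM, the DESeq2 1.42.0 Wald test, the edgeR exact test, limma-voom, no filter beyond a count above 0, a filter of 5 CPM in 2 libraries, the replicate number as a block, and each library left out in turn. Others were limma on log2(RPKM + 1), with and without a filter of RPKM 1 in 2 libraries, and on log2(RPKM + 0.1) with that filter. A test against a minimum fold of 1.5, a log2 fold of at least 1, and the 10 most abundant genes left out were also used. A biological coefficient of variation of 0.1 or 0.2, assumed in place of the estimated 0.028, was added after the data had been seen. So was leaving out each library for most genes named after their values were seen.

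The test was run before use on simulated counts with the means, depths and estimated spread of these libraries. Changed genes were drawn from those with a mean of at least 5 CPM. Of 50 genes changed 1.25-fold among 13523, 19 were recovered, of 50 changed 1.5-fold 45 were, and all 50 changed 2-fold and all 50 changed 4-fold were. There were 3 false calls among the unchanged genes, and in simulated libraries with no change 0 of 13271 genes were called. These figures hold for a spread as small as that of these libraries. They do not describe separate cultures, and the recovery does not describe genes of lower abundance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.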

Results

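Gene expression was profiled in CAL-27 cells, an oral squamous cell carcinoma line, after infection with an empty lentiviral vector or with a lentivirus carrying ZNF750. ZNF750 is a zinc finger transcription factor of stratified epithelium that promotes keratinocyte differentiation. The comparison asks which transcripts differ when the gene is introduced into these tumour cells. Each group had 2 libraries of 8109573 to 8944858 counted reads, with 20433 and 20336 genes detected in the vector libraries and 20975 and 21148 in the ZNF750 libraries. All fold changes below are log2 values for ZNF750 minus vector with their standard error, and n = 2 libraries per group throughout.

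ZNF750 (ENSG00000141579; GRCh38 chromosome 17, 82829435 to 82840578, minus strand) was close to undetected in vector cells and rose in ZNF750 cells. Its counts were 2 and 2 in the vector libraries and 67 and 77 in the ZNF750 libraries, or 0.227 and 0.237 against 8.22 and 9.16 CPM. The log2 fold change was 5.14 ± 0.40 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.24e-35). Because the vector libraries held only 4 counts together, the ratio of summed counts scaled for depth, 37.5 with an exact 95% interval of 14.3 to 139, describes the size better than the fitted value. In the ZNF750 libraries its counted level was modest, as only 27.9% of tested genes had a lower mean level. With the counting tool and strand setting unknown, reads of this gene may have been missed, so its abundance in the cells is uncertain.

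**Figure D1:**
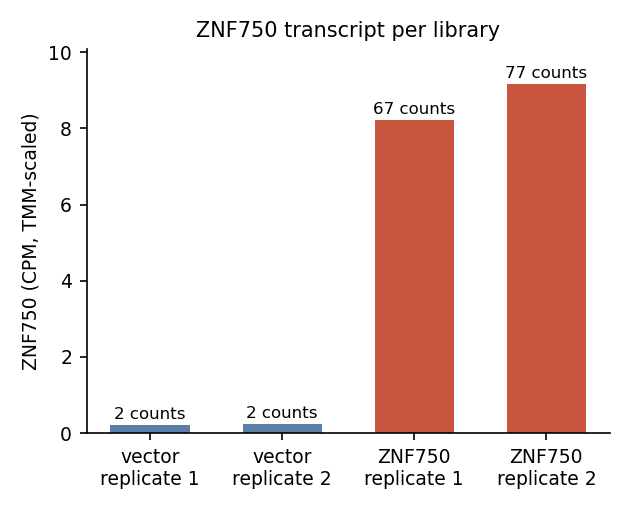
ZNF750 level in each of the 4 libraries, in TMM-scaled CPM, with the raw count above each bar. The vector libraries reached 0.227 and 0.237 CPM and the ZNF750 libraries 8.22 and 9.16 CPM.

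A large part of the transcriptome differed between the groups. Of 13523 genes tested, 4651 rose and 4624 fell, together 9275 or 68.6%, while 4248 did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg). Many differences were small: 3337 changed genes had an absolute log2 fold change under 0.5, and 2722 reached at least 1, of which 1707 rose and 1015 fell. Of 710 long intergenic and antisense RNAs tested, 298 rose and 79 fell, with the limit that overlapping genes on opposite strands cannot be told apart here. Libraries of a group were almost alike, with Pearson r = 0.9936 between the vector and 0.9939 between the ZNF750 libraries across genes, against 0.9322 to 0.9338 between groups. A chi-square of counts per degree of freedom was 1.45 and 1.55 within groups, above counting noise, and 67.6 to 70.66 between them. The 2 libraries of a group did not overlap those of the other at 83% of tested genes, where chance gives 33.3%.

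Such a count depends on the small spread. With a biological coefficient of variation of 0.2 assumed in place of the estimated 0.028, chosen after the data had been seen, 3629 genes passed, 2058 higher and 1571 lower. The balance of rises and falls depended on scaling: 50.1% of changed genes were higher with TMM factors and 60.5% with upper-quartile factors, which move the median of all tested genes from 0.008 to 0.136. Several library measures moved with the group. The share of counts from mitochondrially encoded genes was 1.18% and 1.17% in vector and 1.88% and 1.70% in ZNF750 libraries, that of the 10 most abundant genes 4.18% in each vector library against 4.85% and 4.72%, and that of protein-coding genes 98.96% and 98.94% against 98.68% and 98.69%.

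Among the 12 largest rises, PADI3, which citrullinates hair and epidermal structural proteins, went from 3.08 ± 0.51 to 70.9 ± 3.69 CPM (SD; log2 fold change 4.52 ± 0.13). CYP24A1, the vitamin D catabolic enzyme, rose from 1.80 ± 0.14 to 41.5 ± 2.93 CPM (4.52 ± 0.17), and CYP1A1, a target of the aryl hydrocarbon receptor, from 1.68 ± 0.03 to 24.4 ± 2.62 CPM (3.85 ± 0.20). The alarmins S100A8 (3.85 ± 0.14) and S100A7 (3.72 ± 0.23), the nerve growth factor receptor NGFR (3.71 ± 0.17), CLIC3 (4.10 ± 0.22) and the histone gene H2BC21 (3.67 ± 0.13) rose as well. ADGRF5 (4.94 ± 0.32), ALDH3B2 (4.82 ± 0.31), TP53INP1 (3.65 ± 0.31) and SERPINA5 (3.64 ± 0.29) completed the 12, each with a vector mean below 1 CPM. Their folds depended on single vector libraries: without vector replicate 1 they were 4.39, 4.2, 5.24 and 4.17, and without vector replicate 2 they were 5.72, 5.79, 2.91 and 3.24, in the same order.

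Among the falls, FST led with a drop from 166.9 ± 1.33 to 7.90 ± 0.77 CPM (-4.40 ± 0.09). It encodes follistatin, an extracellular inhibitor of activin. Many of the others are genes of DNA replication or entry into S phase: E2F2 (-3.59 ± 0.28), CDC25A (-3.46 ± 0.17), CLSPN (-3.36 ± 0.11), TYMS (-3.21 ± 0.08), RRM2 (-3.16 ± 0.06), MCM10 (-3.04 ± 0.15), CDC45 (-3.02 ± 0.08) and CCNE2 (-2.98 ± 0.26). The metallothionein MT1M (-3.38 ± 0.19), FAM111B (-3.35 ± 0.11) and WDR62 (-3.32 ± 0.14) also fell. The largest adjusted p among these 24 genes was 4.79e-28 (edgeR quasi-likelihood, Benjamini-Hochberg). MT1M, S100A7 and H2BC21 belong to families of similar sequence, so their levels are uncertain.

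**Figure D2:**
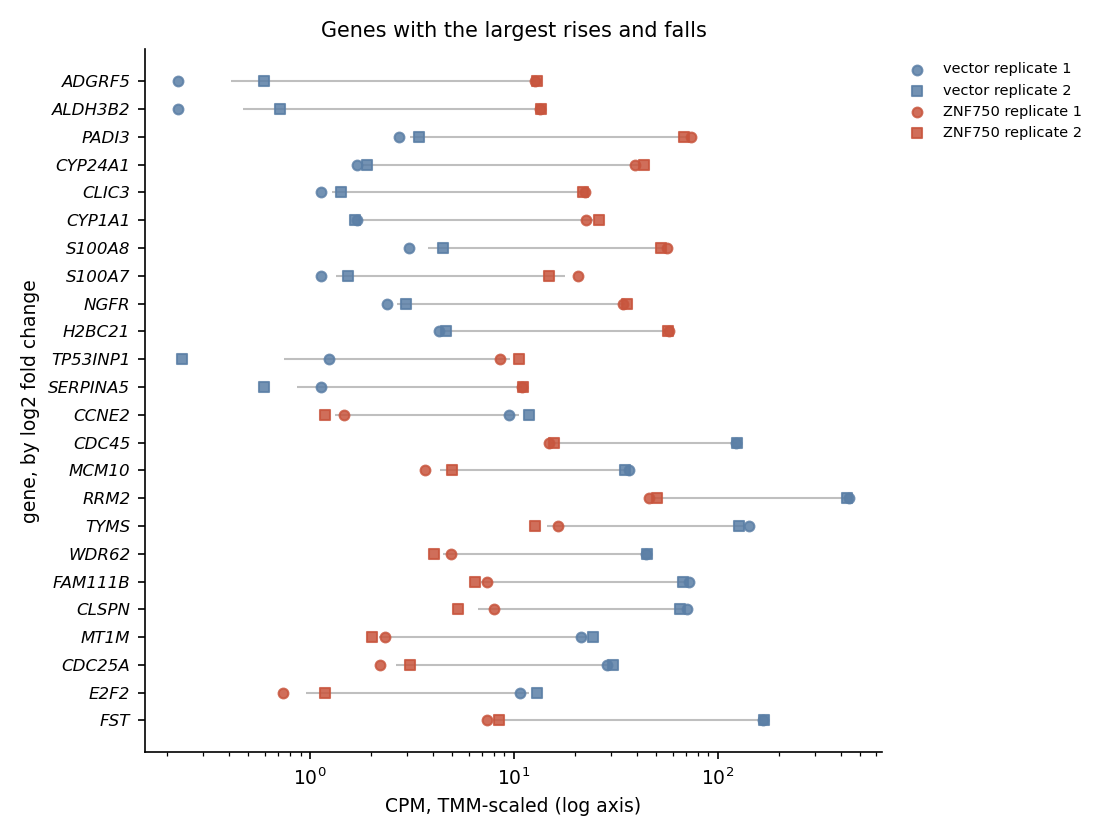
TMM-scaled CPM on a log axis in each of the 4 libraries for the 12 genes with the largest rises and the 12 with the largest falls, ordered by log2 fold change, with a line between group means. By the selection rule, both ZNF750 libraries lie on the same side of both vector libraries for every gene shown, from ADGRF5 (4.94) to FST (-4.40).

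Proliferation genes fell as a block. All 45 measured genes of DNA replication and S phase fell, with a median of -2.14 (0 rose; adjusted over the list alone, 45 fell). Examples were MCM7, a subunit of the replicative helicase, from 841.5 ± 4.03 to 151.2 CPM (-2.48 ± 0.05), MCM4 (-2.58 ± 0.06), MCM5 (-2.47 ± 0.06) and RRM2, the ribonucleotide reductase subunit. All 43 mitosis genes fell too, with a median of -1.94 (adjusted over the list alone, 43), among them MKI67 (-2.28 ± 0.06), TOP2A (-1.89 ± 0.05), UBE2C (-2.42 ± 0.07) and ANLN (-2.15 ± 0.06). Camera placed both lists below other genes, with Benjamini-Hochberg adjusted p = 9.01e-70 for replication and 2.74e-55 for mitosis. Neither call held with a correlation estimated from these libraries (adjusted p = 0.0891 and adjusted p = 0.0908 with an estimated correlation). With the assumed variation of 0.2, 45 of 45 and 42 of 43 still fell.

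Inhibitors of the cycle and p53 target genes tended upwards, with 18 of 30 higher, 5 lower and 7 not passing (adjusted over the list alone, 19 and 5; median 0.38). GDF15, a stress-induced cytokine of the TGF-beta family, rose from 58.6 ± 0.72 to 655.1 CPM (3.48 ± 0.06). The antiproliferative genes BTG2 (2.61 ± 0.07) and BTG1 (1.22 ± 0.06) and the CDK inhibitor CDKN1A (1.80 ± 0.06) rose. MDM2, a main p53 target, fell (-0.30, chosen after its values were seen). The list was called higher by camera (Benjamini-Hochberg adjusted p = 5.46e-05; adjusted p = 0.101 with an estimated correlation).

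Genes of squamous differentiation gave a mixed picture. Of 50 terminal differentiation genes only 22 were expressed enough to test, and of these 15 rose, 2 fell and 5 did not pass (adjusted over the list alone, 15 and 2; median 0.68). The protease inhibitors CSTB (0.87 ± 0.05) and SERPINB3 (2.06 ± 0.16) and the surface protein LYPD3 (1.14 ± 0.07) rose, and the lipoxygenase ALOXE3 fell (-1.53 ± 0.16), as did the suprabasal keratin KRT13 (-3.80 ± 0.46, from 4.41 ± 0.30 to 0.305 ± 0.26 CPM, singled out after its values were seen). The size of the KRT13 fall is uncertain, as it rests on 4 and 1 counts in the ZNF750 libraries: it was -5.05 without ZNF750 replicate 1 and -3.13 without ZNF750 replicate 2. Major cornified envelope genes had too few counts to test, with at most 4 counts for IVL, 5 for FLG and 0 for LORICRIN in any library. Camera did not call the list (Benjamini-Hochberg adjusted p = 0.0562, and 0.339 with an estimated correlation). It passed without vector replicate 1 (adjusted p = 0.0395) or without ZNF750 replicate 2 (adjusted p = 0.0388), in a range of 0.0388 to 0.339 over 9 other camera settings.

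Regulators of differentiation, mostly transcription factors, were higher at 13 of 18, lower at 2 and not past the threshold at 3 (adjusted over the list alone, 13 and 2; median 0.66). The receptor NOTCH3 rose from 21.2 ± 0.74 to 175.8 CPM (3.05 ± 0.08) and its target HES1 from 62.6 ± 0.71 to 458.2 CPM (2.87 ± 0.06), with ELF3 (1.36 ± 0.07) and CEBPB (0.88 ± 0.05) also higher. KLF4, itself a known partner of ZNF750, rose by 0.64 (named after its value was seen). Camera called this list higher (Benjamini-Hochberg adjusted p = 4e-07; adjusted p = 0.101 with an estimated correlation). Basal and progenitor genes split, with 10 of 26 higher, 13 lower and 3 not passing (adjusted over the list alone, 10 and 13), or 13 higher and 11 lower with upper-quartile factors. KRT17 rose (2.10 ± 0.05), whereas the hemidesmosomal collagen COL17A1 (-1.30 ± 0.05), CAV1 (-1.79 ± 0.05) and HMGB2 (-1.81 ± 0.07) fell, and TP63, the basal lineage regulator, stood at 0.01 without passing. That list was not called (camera, Benjamini-Hochberg adjusted p = 0.327).

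Epithelial junction genes were likewise divided, 17 of 32 higher, 10 lower and 5 not passing (adjusted over the list alone, 17 and 10; median 0.18). E-cadherin (CDH1, 1.20 ± 0.05), CLDN4 (1.08 ± 0.05), CLDN7 (1.83 ± 0.11) and plakoglobin (JUP, 1.08 ± 0.05) rose. The list did not pass (camera, Benjamini-Hochberg adjusted p = 0.0562, and 0.224 with an estimated correlation), but it passed without ZNF750 replicate 1 (adjusted p = 0.0448, in a range of 0.0428 to 0.224 over 9 other camera settings). In the fixed list of 7 ZNF750 partners and corepressors, CTBP1 (-0.43 ± 0.06) and CTBP2 (-0.31 ± 0.07) fell, HDAC1 (0.20 ± 0.05) and ZMYM3 (0.30 ± 0.08) rose, and KDM1A (0.02 ± 0.05) and RCOR1 (0.12 ± 0.10) did not pass. The ZMYM3 call was lost with the DESeq2 Wald test, and 0 of the 7 passed with an assumed variation of 0.2. HDAC2 fell (-0.15 ± 0.06), a call lost without vector replicate 1 (adjusted p = 0.0842) and without ZNF750 replicate 2 (adjusted p = 0.0682, edgeR quasi-likelihood, Benjamini-Hochberg), in a range of 0.0104 to 0.759 over 18 alternatives. With upper-quartile factors HDAC2 did not pass and KDM1A and RCOR1 passed as higher. This list, with 2 higher, 3 lower and 2 not passing (adjusted over the list alone, 2 and 3), or 4 and 2 with upper-quartile factors, had a median of 0.02, a mean of -0.04 and a camera direction downwards (Benjamini-Hochberg adjusted p = 0.936).

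Inflammatory genes rose broadly. In the inflammation and NF-kB list 29 of 34 were higher, 3 lower and 2 did not pass (adjusted over the list alone, 29 and 3; median 1.15). S100A9 rose from 60.2 ± 0.83 to 636.2 ± 12.1 CPM and the cytokine IL1B from 235.5 ± 12.5 to 944.8 ± 11.5 CPM. IL1A (2.06 ± 0.05) and the chemokine CCL20 (2.40 ± 0.07) rose as well. The 3 that fell were CSF2 (-2.48), NFKB1 (-0.54) and CSF3 (-1.24 ± 0.50), named after their values were seen. The groups overlapped for CSF3, with 10 and 15 counts in the vector and 0 and 10 in the ZNF750 libraries. Its call was lost without ZNF750 replicate 1 (-0.29, adjusted p = 0.685) and without vector replicate 2 (-0.91, adjusted p = 0.32, edgeR quasi-likelihood, Benjamini-Hochberg), and without ZNF750 replicate 2 its ZNF750 group held 0 counts. Camera called the list higher (Benjamini-Hochberg adjusted p = 6.23e-21; adjusted p = 0.101 with an estimated correlation).

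Immediate early and AP-1 genes behaved similarly, with 22 of 28 higher, 2 lower and 4 not passing (adjusted over the list alone, 22 and 2; median 1.05). The nuclear receptor NR4A1 (3.19 ± 0.08), EGR2 (3.49 ± 0.11) and JUNB (1.56 ± 0.05) rose, while FOSL1 (-2.12 ± 0.05) and CCND1 (-1.21), which encodes cyclin D1 and is named after its value was seen, fell. Camera called it higher (Benjamini-Hochberg adjusted p = 2.03e-20; adjusted p = 0.101 with an estimated correlation). The interferon response list had 27 of 43 higher, 5 lower and 11 not passing (adjusted over the list alone, 27 and 5; median 0.52). IFITM3 (1.28 ± 0.05), IFITM1 (1.90 ± 0.09) and IFIT2 (1.52 ± 0.07) rose, but MX1 (0.06), picked after its value was seen, did not pass. That list was called higher too (camera, Benjamini-Hochberg adjusted p = 0.000233; adjusted p = 0.156 with an estimated correlation). IRF9, a member with at most 7 counts in any library, was too low to test, which does not show that it is barely expressed.

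Angiogenesis and vascular signalling genes changed in both directions, 26 of 41 higher, 11 lower and 4 not passing (adjusted over the list alone, 26 and 12; median 0.30). The chemokines CXCL8 (1.81 ± 0.05) and CXCL1 (1.12 ± 0.06) and the matricellular factor CCN2 (1.38 ± 0.05) rose. THBS1, which encodes the angiogenesis inhibitor thrombospondin-1, fell from 1534.6 ± 5.95 to 428.2 CPM (-1.84 ± 0.05). The growth factors FGF2 (-2.03) and VEGFC (-0.72) and the receptor NRP1 (-1.44) fell too, while VEGFA rose (0.79). These were named after their values were seen. Camera called the list higher (Benjamini-Hochberg adjusted p = 0.0231; adjusted p = 0.167 with an estimated correlation). Hypoxia and glycolysis genes were higher at 18 of 29, lower at 6 and not past the threshold at 5 (adjusted over the list alone, 18 and 6; median 0.45), with ALDOC (2.14 ± 0.06), DDIT4 (1.63 ± 0.05), P4HA1 (1.33 ± 0.05) and NDRG1 (1.14 ± 0.05) among the rises (camera, Benjamini-Hochberg adjusted p = 7.07e-06; adjusted p = 0.101 with an estimated correlation). Other glycolytic enzymes of the list, picked after their values were seen, were divided. ALDOA (0.77), ENO2 (0.57), PGK1 (0.44) and GAPDH (0.10) rose. PGAM1 (-0.33), HK2 (-0.27), ENO1 (-0.26) and PKM (-0.21) fell, and LDHA, HK1 and PFKP did not pass.

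Mesenchymal and invasion genes included 19 of 34 that rose, 9 that fell and 6 that did not pass (adjusted over the list alone, 20 and 9; median 0.66). The collagens COL5A1 (1.52 ± 0.05) and COL6A1 (0.82 ± 0.05) and the membrane protease MMP14 (1.02 ± 0.05) rose. Of members named after their values were seen, N-cadherin (CDH2, -0.67) and SNAI2 (-0.78) fell, while SNAI1 (1.33) and VIM (0.54) rose. TWIST1 and ZEB1 did not pass. Other matrix metalloproteases, also picked after their values were seen and low in level, were divided. MMP1 (-1.93), MMP3 (-4.68), MMP13 (-1.45) and MMP10 (-0.87) fell, while MMP2 (1.55) and MMP7 (1.30) rose. The size of the MMP3 fall is uncertain, as its mean went from 1.92 CPM in vector to 0.059 CPM in ZNF750 libraries. The list was called higher (camera, Benjamini-Hochberg adjusted p = 0.00306; adjusted p = 0.137 with an estimated correlation).

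Of 24 cholesterol and sterol synthesis genes 19 rose, 2 fell and 3 did not pass (adjusted over the list alone, 19 and 2; median 0.91). INSIG1 (2.10 ± 0.07), the methylsterol oxidase MSMO1 (1.92 ± 0.07) and the sterol reductase TM7SF2 (2.37 ± 0.11) were higher (camera, Benjamini-Hochberg adjusted p = 3.21e-12; adjusted p = 0.101 with an estimated correlation). The NRF2 and oxidative stress list had 11 of 22 higher, 5 lower and 6 not passing (adjusted over the list alone, 11 and 5), with FTH1 (0.68 ± 0.04) up and GCLM (-1.06 ± 0.09) down, and was not called (camera, Benjamini-Hochberg adjusted p = 0.233).

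Nuclear genes of oxidative phosphorylation were lower at 16 of 33 and higher at 5 (12 not passing; adjusted over the list alone, 5 higher and 16 lower), or lower at 11 and higher at 10 with upper-quartile factors. CYC1 (-0.91 ± 0.05), CYCS (-0.87 ± 0.05) and ATP5F1B (-0.75 ± 0.04) fell, while the mitochondrially encoded share of counts was higher in the same libraries. Camera did not call the list (Benjamini-Hochberg adjusted p = 0.0694, and 0.658 with an estimated correlation), though it passed without vector replicate 2 (adjusted p = 0.0403) or without ZNF750 replicate 1 (adjusted p = 0.0339), in a range of 0.000558 to 0.658 over 9 other camera settings. Ribosomal protein genes showed small shifts, 27 of 47 higher, 5 lower and 15 not passing (adjusted over the list alone, 27 and 5; median 0.11), or 38 higher and 0 lower with upper-quartile factors. RPS27 (0.45 ± 0.05) and RPL13 (0.42 ± 0.04) rose, 0 of the 47 passed with an assumed variation of 0.2, and the list's adjusted p was 0.0516 (camera, Benjamini-Hochberg), with 0.762 under an estimated correlation. It passed without vector replicate 1 (adjusted p = 0.0395) or without ZNF750 replicate 2 (adjusted p = 0.00589), in a range of 0.00589 to 0.762 over 9 other camera settings.

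Of 25 unfolded protein and amino acid stress genes 11 rose and 14 fell (adjusted over the list alone, 11 and 14; median -0.23). The serine synthesis enzyme PSAT1 (-2.15 ± 0.06), asparagine synthetase ASNS (-1.54 ± 0.08), the mitochondrial serine hydroxymethyltransferase SHMT2 (-0.83 ± 0.05) and the tRNA exporter XPOT (-1.08 ± 0.06) fell. The members of the endoplasmic reticulum, picked after their values were seen, mostly rose: DNAJB9 (1.24), HERPUD1 (0.98), HSPA5 (0.51), DNAJC3 (0.42), PDIA6 (0.32), HSP90B1 (0.21), PDIA4 (0.20) and CALR (0.18) were higher, while SDF2L1 (-0.82) and HYOU1 (-0.17) fell. The HYOU1 call was lost without vector replicate 2 (adjusted p = 0.0665). The list as a whole was not called (camera, Benjamini-Hochberg adjusted p = 0.121). XBP1, a member that most human cells express, had 0 counts in all 4 libraries, so a gene with few or no counts in this table is not shown to be silent.

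Of 22 replication-dependent histone genes only 9 could be tested, and 8 of them rose, 0 fell and 1 did not pass (adjusted over the list alone, 8; median 1.33). H2BC21, H2AC6 (3.03 ± 0.13), H2BC5 (2.57 ± 0.16) and H1-2 (1.43 ± 0.13) rose, all from vector means under 11 CPM. Most replication-dependent histone transcripts lack a poly(A) tail, and the sources used here do not say whether RNA was selected by it, so it is open how far these counts represent the histone transcripts of the cells. The list was called higher (camera, Benjamini-Hochberg adjusted p = 0.000293; adjusted p = 0.13 with an estimated correlation).

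Most markers of other cell types were too low to test, and each of these lists had too few measured members for a list test. Of 12 fibroblast markers 4 were measured and rose (adjusted over the list alone, 4): COL1A1, from 13.4 ± 2.14 to 46.2 CPM (1.79 ± 0.11), FBN1 (1.88 ± 0.23), COL1A2 (1.45 ± 0.25) and PDGFRB (1.28 ± 0.22). DCN, COL3A1 and PDGFRA had 0 counts in every library. Of 10 leukocyte markers 3 were measured, of which CD14 (1.96 ± 0.32) and LAPTM5 (0.59 ± 0.12) rose and CORO1A (-0.05 ± 0.19) did not pass. Endothelial EGFL7 rose (1.27 ± 0.11) and CDH5 fell (-0.43 ± 0.13). The CDH5 call was lost without vector replicate 2 (adjusted p = 0.0934) and without ZNF750 replicate 1 (adjusted p = 0.0546; edgeR quasi-likelihood, Benjamini-Hochberg), in a range of 0.000381 to 0.335 over 18 alternatives. Melanocyte PMEL rose (0.79 ± 0.28), a call lost without vector replicate 1 (adjusted p = 0.0978) and without ZNF750 replicate 1 (adjusted p = 0.112), in a range of 0.00211 to 0.232 over 17. MITF (-0.28 ± 0.25) did not pass. KRT8 (-0.37 ± 0.04), LHX1 (-0.42 ± 0.15) and KRT18 (-0.11 ± 0.05), markers of simple epithelium and kidney cells, fell. LHX1 did not pass without ZNF750 replicate 1 (adjusted p = 0.0573) or with upper-quartile factors, in a range of 0.00607 to 0.356 over 18 alternatives. KRT18 did not pass without vector replicate 1 (adjusted p = 0.142) or ZNF750 replicate 2 (adjusted p = 0.313), in a range of 0.00161 to 0.827, and stood at 0.02 with upper-quartile factors. Counts adjusted over the list alone were the same for these lists.

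Of the 20 lists tested, camera with the preset correlation called 10 higher and 2 lower. With a correlation estimated from the 4 libraries camera called 0, the lowest adjusted p was 0.0891, and 8 had an unadjusted p under 0.05, 6 of them higher and 2 lower. Fry, which asks whether a list's genes move one way on balance without comparing them with other genes, called 18. With the assumed variation of 0.2, the numbers of genes higher and lower were 21 and 1 for inflammation, 18 and 2 for immediate early genes, 16 and 0 for sterol synthesis, 15 and 6 for mesenchymal genes, 14 and 2 for interferon, 12 and 7 for angiogenesis, 9 and 2 for p53 targets, 9 and 2 for terminal differentiation, 8 and 1 for hypoxia, 7 and 0 for differentiation regulators and 6 and 0 for histones.

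**Figure D3:**
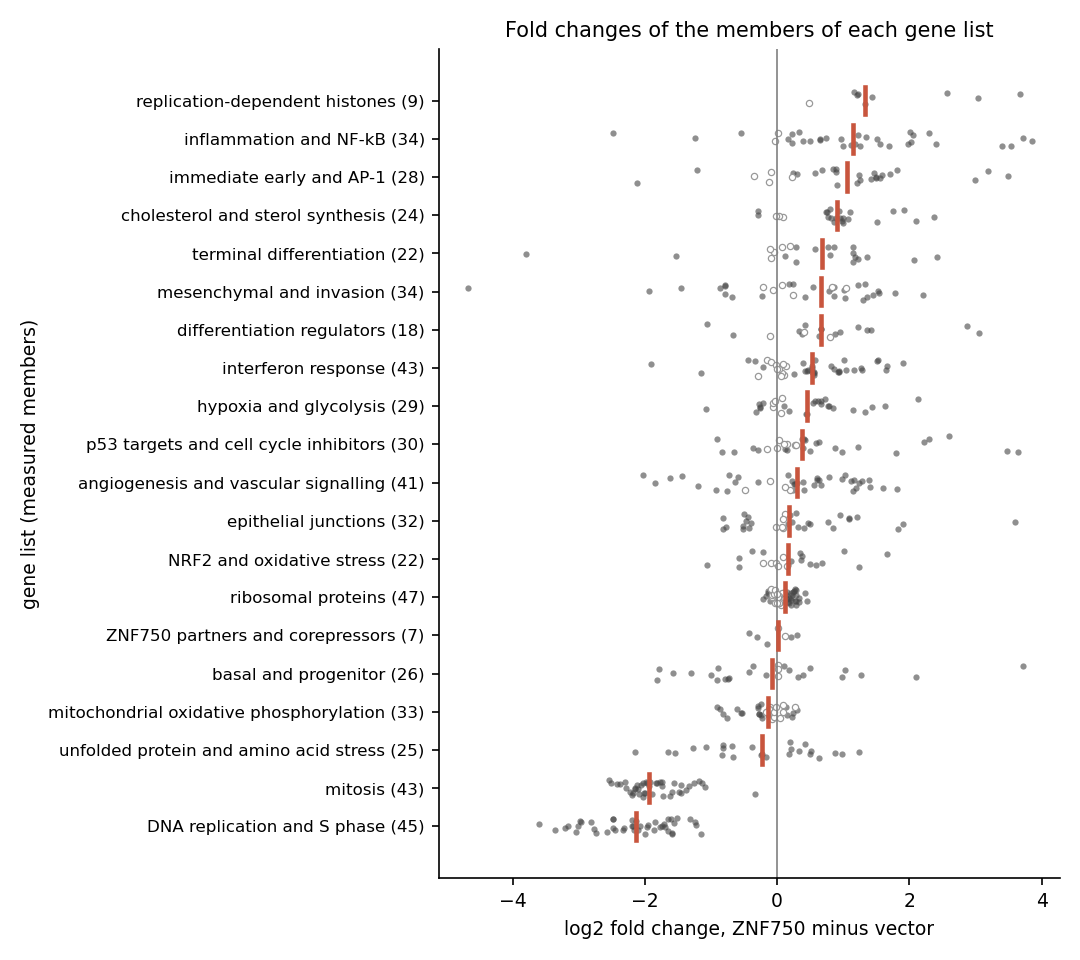
Log2 fold change (ZNF750 minus vector) of each measured gene in the 20 tested lists, ordered by list median (red bar), with the number of measured genes in brackets. Filled points passed the adjusted threshold and open points did not; the replication (median -2.14) and mitosis (median -1.94) lists lie apart below 0.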

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

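Alternatives with an assumed biological coefficient of variation were added after the results had been seen; all others here were planned. The count of 9275 changed genes fell to 3629 (2058 higher, 1571 lower) with an assumed variation of 0.2, to 3639 (2037 and 1602) against a minimum fold of 1.5, and to 2722 (1707 and 1015) at a log2 fold of at least 1. All of these genes were among those called before. That follows for the fold settings, which only ask for a larger effect. For the assumed variation, far above the estimated 0.028, nearly every p-value was bound to grow. The nesting of these calls is therefore no evidence that they are robust. An assumed variation of 0.1 gave 6907. The DESeq2 Wald test called 6520 genes, with 2928 higher, and the cause was not tested. Leaving out each library in turn gave 8298 to 8539 changed genes, and in those fits the lone library of a group is assumed to vary like the others. The replicate number as a block gave 9157 genes and 13 lists instead of 12, the list gained being ribosomal proteins (adjusted p = 0.0454, camera, Benjamini-Hochberg). Same-numbered libraries did not deviate together (correlation across genes -0.024), so the numbers were not used to pair samples. Tests on RPKM called 7521 to 8778 genes.

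Of 2139 values of named genes under 18 alternatives, 2077 kept their direction and side of the threshold, 53 lost their call, 2 gained one and 7 changed sign. The values of opposite sign, for which the cause was not tested, were near 0 and not past the threshold. KDM1A was -0.017 with the DESeq2 Wald test, -0.016 with no filter and between -0.022 and 0.027 with a library left out, CORO1A 0.081 with upper-quartile factors and 0.002 at 5 CPM or more, MITF between -0.663 and 0.025 with a library left out, and KRT18 0.017 with upper-quartile factors. List tests called 12 lists, but 0 with an estimated correlation. For sterol synthesis that estimate was -0.036, below the preset 0.01, yet its camera adjusted p (Benjamini-Hochberg) went from 3.21e-12 to 0.101. Estimates were also below 0.01 for histones, angiogenesis, mesenchymal genes, p53 targets, hypoxia and differentiation regulators. They were above it for replication, mitosis, interferon, inflammation and immediate early genes. A higher correlation therefore cannot explain the loss in the lists below 0.01. The 2 forms also differ in degrees of freedom, which the preset form takes from the genes and the estimated form from the 4 libraries. With so few, small p-values are hard to reach for any list, so a lost call does not show correlation within that list. How much each difference contributed was not tested. The list of ZNF750 partners changed direction at 5 CPM or more (adjusted p = 0.926) and without vector replicate 1, with adjusted p from 0.844 to 0.997 over the libraries left out. CD14, PMEL and MITF did not meet the 5 CPM filter. Depth limits genes near 1 CPM, which corresponds to about 8.15 to 8.81 counts.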

Other observations

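The 10 gene lists in the next paragraphs were written after the gene results had been seen, so their p-values are not independent evidence, and of the tests further on only that of gene length and GC content was set out before its result was seen. Notch pathway genes rose at 9 of 11 measured (median 1.09; camera, Benjamini-Hochberg over 9 lists, adjusted p = 3.1e-06; adjusted p = 0.132 with an estimated correlation), with NOTCH3 and HES1 joined by NRARP (1.46) and DLL1 (1.09), while LFNG fell (-0.88). Complement genes rose at 11 of 12 (median 1.58; adjusted p = 1.17e-10, camera, Benjamini-Hochberg; adjusted p = 0.0776 with an estimated correlation). C3 went from 1134.9 to 3579.7 CPM (1.66), C1R (1.48), C1S (1.51), CFB (1.67) and SERPING1 (2.63) rose, and CD59 fell (-0.53). Antigen presentation genes rose at 13 of 16 (median 0.68; adjusted p = 2.26e-08, camera, Benjamini-Hochberg; adjusted p = 0.132 with an estimated correlation), including CD74 (1.12) and HLA-DRA (1.34), while their activator CIITA fell (-0.66). Lysosomal genes rose at 21 of 28 and fell at 2 (median 0.49; adjusted p = 4.97e-09, camera, Benjamini-Hochberg; adjusted p = 0.132 with an estimated correlation), led by GAA (1.34), LIPA and the cathepsins CTSB (1.23) and CTSD (1.23). Of 8 aryl hydrocarbon receptor targets 4 rose, CYP1A1, CYP1B1 (3.23), TIPARP (0.95) and AHRR (1.79), and 2 fell, NQO1 (-0.58) and SLC7A5 (-0.18), with 2 not passing (list adjusted p = 0.00465, camera, Benjamini-Hochberg; adjusted p = 0.269 with an estimated correlation). The AHRR fold was 1.31 without vector replicate 1 and 2.44 without vector replicate 2.

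All 20 measured ribosome biogenesis genes fell (median -0.94; camera, Benjamini-Hochberg adjusted p = 9.67e-18; adjusted p = 0.0776 with an estimated correlation), among them NOP56 (-1.93), NCL (-1.31) and DKC1 (-1.59). Cytosolic aminoacyl-tRNA synthetases fell at 17 of 20 (median -0.68; adjusted p = 4.17e-08, camera, Benjamini-Hochberg; adjusted p = 0.0776 with an estimated correlation), with VARS1 (-1.25) and MARS1 (-1.21) lowest and QARS1 higher (0.42). MYC, a known driver of ribosome biogenesis, rose slightly (0.39). Metallothioneins fell at 4 of 5, including the abundant MT2A (-0.93), while MT1X rose (0.68; list adjusted p = 0.0037, camera, Benjamini-Hochberg; adjusted p = 0.147 with an estimated correlation), though reads can be shared within this family. Mitochondrially encoded genes rose at 11 of 12, such as MT-ND1 (1.06), with adjusted p = 5.69e-06 (camera, Benjamini-Hochberg; adjusted p = 0.269 with an estimated correlation). Stress keratins split: KRT17 (2.10) and KRT16 (1.73) rose, KRT6A fell (-2.50) and KRT6B (-0.24) did not pass, though it passed as lower without vector replicate 2 (adjusted p = 0.0385) or without ZNF750 replicate 2 (adjusted p = 0.0209). With an estimated correlation camera called 0 of the 9 lists tested, 3 of which had an unadjusted p under 0.05. The direction of each list's median was the same with DESeq2 factors, upper-quartile factors and library size alone.

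The fall of the 88 cell cycle genes was far outside what scaling could give. Their median minus that of all other genes was -2.01, where a scaling error would move all genes alike. Its SE of 0.067 was taken across the 88 genes as if they were independent, and does not measure the spread between libraries. After a trend on gene length and GC content fitted to the other genes was removed, their median was -1.98 (SE 0.068, again across genes), which argues against that trend as the cause. Within a group the cell cycle genes differed between libraries by a median of at most 0.021, but the labels do not say that each group had more than a single culture, so density or growth phase and ZNF750 cannot be told apart. That ZNF750 slows cycling of these cells is a hypothesis which these libraries do not decide, since sparse against confluent flasks could give the same pattern, and it would need separate cultures of each group at matched density with cell counts.

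The small spread within groups may come from libraries made from the same culture or RNA. Immediate early genes, which respond to handling, had a median within-group chi-square of 4.25, against 3.35 for 10000 lists matched on abundance, a ratio of 1.27 at percentile 81.3. Counting error alone would give 1.39, all genes had 1.78 and cell cycle genes 1.69, so immediate early genes varied beyond counting error, as did the lists of their abundance. A ratio under 1.5 was taken as what a single culture per group would give, and it was found, but separate cultures handled side by side could give it too. No biological explanation of the spread was tested. If that source applies, the p-values in the comparison describe libraries rather than cultures.

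The rise of COL1A1, FBN1, COL1A2 and PDGFRB raised the question of fibroblasts in the ZNF750 cultures. COL1A1 rose by 32.78 CPM, whereas COL3A1, DCN and LUM, abundant in fibroblasts, together moved by a share of -0.0012 of that rise, with COL3A1 and DCN at 0 counts in every library. VIM stood at 7.60 CPM in vector and 11.06 CPM in ZNF750 cells. These levels argue against admixed fibroblasts, with the reservation that this count table can miss expressed genes. Expression of these genes by the tumour cells themselves remains a hypothesis.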
